A study of Mus musculus with 4 samples.

How the data were processed

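Gene expression was measured in the hippocampus of 4 male mice aged 3 months, 2 wildtype and 2 carrying a Malat1 knockout, each on its own Affymetrix mouse exon array. The labels call the arrays of a group biological replicates, and the series' design text speaks of individual animals. A label calls the RNA neuronal, but the protocols describe dissected hippocampi and no sorting of cells. Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled amplified RNA was made from 100 ng with a 3' in vitro transcription kit. Such a kit copies RNA from the poly(A) tail and yields antisense RNA, whereas arrays of this type carry probes for sense-strand targets. The labels do not say how this was reconciled, so the strand that a row reports on and the evenness of signal along a transcript are open.

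The deposited table holds log2 expression values, per the range and shape of the values themselves (4.16 to 14.26, with array medians between 5.59 and 5.63). The background correction, normalization, summarization and software that the authors used are not given in the sources used here. The genome build is mm9, per the submitters' processing notes. The table has 265511 rows, which are transcript clusters (1 summary value per putative gene) and not exon probesets. The planned test of differential exon usage, and the planned minimum of 3 probesets per gene, were therefore not run, and the planned count of exon probesets became a count of transcript clusters. Array values compress true ratios, so the folds given here are folds of array signal.

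GEO's platform annotation gave 1 gene symbol to 27090 rows, several symbols to 2498 rows and none to 235923 rows. No gene was named from a row with several symbols. The 27090 rows covered 20707 genes, and 20225 of the 20711 Entrez identifiers behind them were in the RefSeq table of assembly GRCm38.p6, which was used only for gene order and chromosome. Rows with a mean over the 4 arrays under the 25th percentile of the singly named rows (5.70 on the log2 scale) were left out. A gene with several remaining rows was represented by the row with the highest mean. This last rule was set once the annotation had shown that 3487 genes have several rows. That left 15995 genes, of which 3183 have more than 1 named row.

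The values were used as deposited. Knockout and wildtype were compared with limma (version 3.58.1, lmFit and eBayes, two-sided, in R 4.3.3) with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The spread was estimated from 2 residual degrees of freedom per gene and a prior worth 2.98 degrees of freedom. The 95% intervals of log2 fold changes come from the same fit and are not adjusted for the number of genes. With 2 arrays per group, the number of arrays limits the precision. The median half-width of these intervals was 0.16 on the log2 scale.

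Gene lists and cell type markers (32 lists) were fixed before the data were examined, as were the tests and the rule for named genes. Blood markers had fewer than 3 measured members, so 31 lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists, beside camera with an estimated correlation and fry. The named genes are Malat1, all genes past the threshold, and the 12 largest log2 fold changes per direction, filled up from genes with an unadjusted p under 0.01 and the same direction in both same-numbered pairs of arrays. In each list the 2 to 4 members with the largest absolute log2 fold change are named, and any Malat1 neighbour could be named.

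On simulated data with the means and spread of the 15995 genes and 200 genes changed, the fit recovered 50.6% of changes of 0.5, 93.7% of changes of 1 and 99% of changes of 2 on the log2 scale, with 8.45 unchanged genes called per simulation. These rates hold where 200 genes change together, changes of 2 and 3 among them, which eases the adjusted threshold. The recovery of a lone change of 0.5 or 1 was not simulated. A single gene with the change of Malat1 was recovered in 92.5% of 200 simulations. A list of the size of the neighbour list shifted by 0.1 was called in 100% of 20 simulations, and 1 of 620 unshifted lists was called. Genes were drawn independently in these simulations, while the estimated correlation within the neighbour list was 0.159 in the data. The simulated shares of called lists therefore do not carry over to correlated lists.

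The series' design text says that knockout and wildtype animals came as littermate pairs, but no label says that the replicate number marks the pair, so the fit with the replicate number as a block was run as an alternative. Other alternatives were quantile normalization, centring of array medians, no filter and a filter at the 50th percentile, an intensity trend in the variance model, the mean over the rows of a gene, every named row on its own, and leaving out each array in turn, with the row of each gene chosen anew or kept. Figures were drawn with matplotlib 3.10.9.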

Results

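Hippocampal RNA from 2 wildtype and 2 Malat1 knockout mice of the C57BL/6 strain was profiled on exon arrays at the level of transcript clusters. Malat1 is an abundant long noncoding RNA that is retained in nuclear speckles, the compartments where splicing factors are stored. The series asked how its loss affects gene expression. All 4 arrays had 265511 values each, with medians of 5.60 and 5.59 in the wildtype arrays and 5.59 and 5.63 in the knockout arrays on the log2 scale. Across 15995 genes, the correlation of log2 values was 0.991 between the wildtype arrays, 0.988 between the knockout arrays and 0.985 to 0.993 between arrays of different genotype. These correlations are across genes, which are not independent replicates. Knockout replicate 2 stood apart. The median absolute difference per gene was 0.076 to 0.083 in its 3 pairs, of which 0.081 was with the other knockout array. In the 3 pairs without it the difference was 0.047 to 0.057, 0.057 between the wildtype arrays and lowest between knockout replicate 1 and wildtype replicate 2.

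Malat1 signal was 6.10-fold lower in the knockout hippocampus (95% interval 5.33 to 6.98). Its log2 signal was 11.22 ± 0.04 (SD, n = 2) in wildtype and 8.61 ± 0.12 (SD, n = 2) in knockout animals, a change of -2.61 ± 0.08 (SE). The drop was -2.67 between the arrays numbered 1 and -2.55 between those numbered 2. It passed the threshold among all genes (limma, adjusted p = 0.00639). Both arrays labelled knockout were low (8.53 and 8.70, against 11.19 and 11.25 in wildtype), which goes with the genotype labels. One transcript cluster carries the Malat1 name, and which part of the gene was deleted is not given in the labels. Whether this row lies within the deleted part, and what its remaining signal reflects, is open. The call depended on having both knockout arrays, since the adjusted p was 0.107 without knockout replicate 1 and 0.0816 without knockout replicate 2, at changes of -2.52 and -2.70; over all alternatives it ran from 1.62e-04 to 0.107.

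Outside Malat1, no gene of the 15995 tested passed the threshold in either direction, and the next smallest adjusted p by limma was 0.832. At an unadjusted p under 0.05 there were 617 genes, where 800 would arise with no difference at all. That count was 1596 without knockout replicate 1, which leaves knockout replicate 2 as the only knockout array, and 451, 758 and 626 without wildtype replicate 1, wildtype replicate 2 and knockout replicate 2. With each gene taken at its brightest row, Malat1 was the only gene with a change over 2-fold. A change over 1.5-fold was seen in 34 genes, 11 higher and 23 lower in the knockout. For 95.9% of the genes the 95% interval lay within 1.5-fold in both directions, and for 99.5% it lay within 2-fold.

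The genes with the largest differences at an unadjusted limma p under 0.01 were of mixed kinds. None of those named here other than Malat1 passed the adjusted threshold. All 129 genes under that p had the same direction in both same-numbered pairs, so the condition on direction left none out. Lower in the knockout were the RNA helicase Ddx6, a component of cytoplasmic processing bodies (log2 fold change -0.65), the thioesterase gene Them4 (-0.61), Lrrc10b (-0.67), the zinc finger gene Zfp964 (-0.66) and the pregnancy-specific glycoprotein Psg16 (-0.73). The same side held the U2 small nuclear RNA copy Rnu2-10 (-0.64), the olfactory receptor Olfr665 (-0.74), the vomeronasal receptor Vmn1r224 (-0.62), and the transcripts A630089N07Rik (-0.79), 4930562C15Rik (-0.74) and 4921517D16Rik (-0.67). Higher in the knockout were Frmd8 (0.57), described below, the zinc finger gene Zfp655 (0.55), Nfatc2ip (0.53), the collagen gene Col6a5 (0.52), the serpin Serpina3j (0.51) and the olfactory receptor Olfr572 (0.51). That side also held Gm4911 (0.90), Epp13 (0.75), Gm7357 (0.74), 4930445K14Rik (0.60), 9530047P18Rik (0.59) and Gm6458 (0.54). The wildtype means of Epp13 (5.67), Serpina3j (5.71) and 4930445K14Rik (5.73) lay near or under the filter level of 5.70. So did the knockout mean of 4921517D16Rik (5.50), and the size of these changes is uncertain. Of the 24 named genes including Malat1, 14 have further transcript clusters under the same symbol. In 12 of the 14 the median change of those other clusters was within 0.2 of 0. In the rest, Gm4911 and Nfatc2ip, it was -0.28 for each, opposite to the rises named above. Olfr665, Olfr572, Rnu2-10 and Vmn1r224 belong to families with near-identical copies, so their probes can share signal. With the mean over its rows, Nfatc2ip stood at -0.01.

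The genes next to Malat1 on chromosome 19 test for a local effect of the deletion. Neat1, the nearest measured gene on 1 side and the long noncoding RNA that builds paraspeckles, was 1.51-fold lower in the knockout (95% interval 1.29 to 1.77), at 8.09 ± 0.07 in wildtype and 7.49 ± 0.15 in knockout arrays (SD, n = 2 each). Frmd8, the next gene along and a FERM-domain protein, was 1.49-fold higher (95% interval 1.31 to 1.69), at 7.07 ± 0.10 and 7.64 ± 0.05 (SD, n = 2 each). Adjusted over the list alone, 2 of the 18 measured neighbours passed the threshold by limma, Frmd8 with an adjusted p of 0.00871 and Neat1 with one of 0.0107. This adjustment was read in the main fit only, so whether it holds under the alternatives is open. Over all genes tested neither passed, with adjusted p values of 0.860 and 1, although they ranked 9th and 16th by p. A second, dimmer transcript cluster under the Neat1 name stood at 0.05, and the mean over both gave Neat1 a value of -0.27.

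As a group, 16 of the 18 measured neighbours lay above 0 and 2 lay below, and the list's median log2 fold change was 0.096. Camera with a preset correlation called the list higher in the knockout (adjusted p = 1.96e-04), and it was the only called list of the 31. The call was lost with an estimated correlation (adjusted p = 0.947 with an estimated correlation) and with fry (adjusted p = 0.874 for a shift in 1 direction). Without knockout replicate 2 the median was 0.071 and camera called none of the 31 lists. Beyond Neat1 and Frmd8, the largest values were those of Ltbp3, which encodes a binding protein of latent TGF-beta (0.20), the Cdc42 effector Cdc42ep2 (0.17), the protease gene Capn1 (0.14) and the chromatin factor Dpf2 (0.14). Slc25a45, Kcnk7, Ehbp1l1 and Pola2 lay between 0.11 and 0.12. Sipa1 and Map3k11 both stood at 0.08, Slc22a20 at 0.09 and Kat5 at 0.04. The values nearest 0 were those of Rela (0.00), Pcnx3 (-0.00), Syvn1 (0.01) and Tigd3 (0.02, 95% interval -0.39 to 0.43). However, 2 dimmer clusters under the Rela name stood at 0.221 and 0.265, and a dimmer Tigd3 cluster at 0.09.

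**Figure D1:**
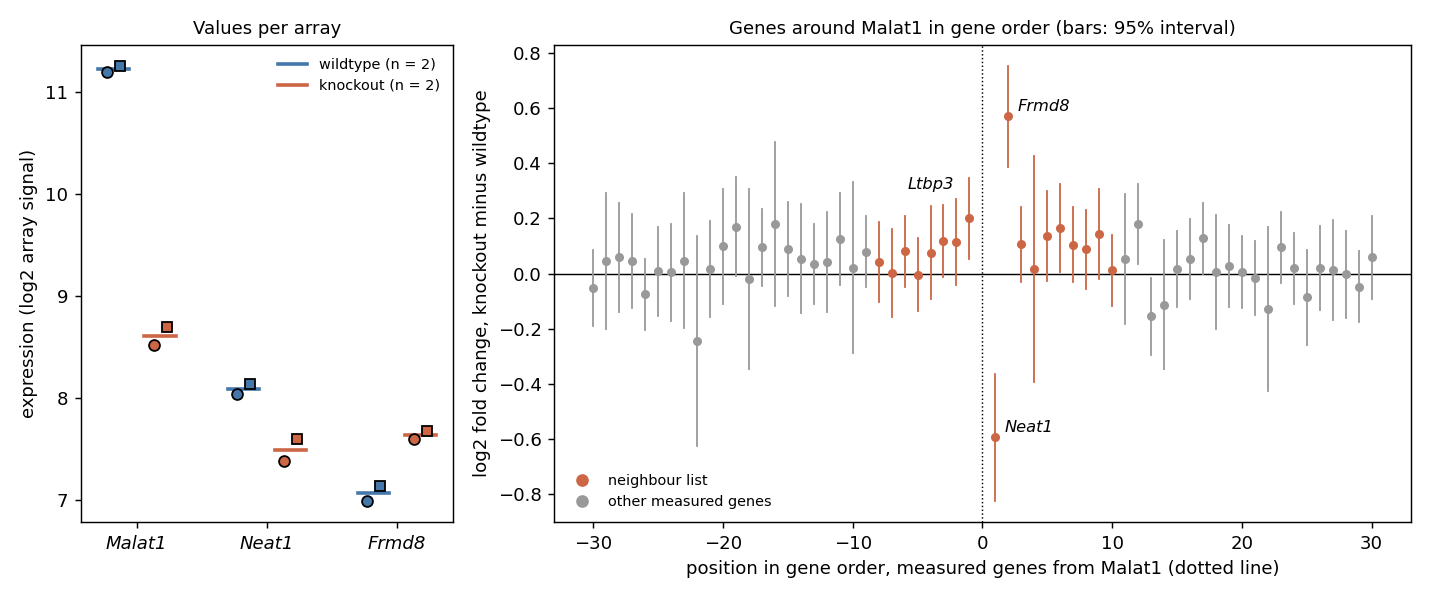
Left, log2 array signal of Malat1, Neat1 and Frmd8 in each array (circles replicate 1, squares replicate 2, lines group means of n = 2). Right, log2 fold change, knockout minus wildtype, with its 95% interval for 30 measured genes on each side of Malat1 in gene order. Malat1 itself, at -2.61, is left off the right panel; Neat1 lies at -0.59 and Frmd8 at 0.57, and the other neighbours (orange) lie near or a little above 0.

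Genes of RNA splicing, the process most often linked with Malat1, showed no difference that passed a test. None of 96 distinct measured genes in the lists of SR proteins and their kinases, hnRNP and tissue splicing regulators, core spliceosome and paraspeckle proteins passed the threshold, over all genes or adjusted over the list alone. At an unadjusted limma p under 0.05 there were 3 hnRNP and tissue regulators and 0 genes in each of the other lists. The list medians were -0.02, -0.01, -0.03 and -0.00, with camera adjusted p values of 0.588, 0.526, 0.237 and 0.809. For 95 of the 96 genes the 95% interval excluded a 1.5-fold change in either direction. Among SR proteins and kinases, the largest values were those of the kinase Clk3 (-0.10) and the neuronal splicing activator Srrm4 (-0.05). Among hnRNP and tissue regulators they were those of Khdrbs1, which encodes Sam68 (0.26), and Hnrnpd (-0.23). In the spliceosome list, the 3' splice site factors U2af2 (-0.31, 95% interval -0.79 to 0.17) and U2af1 (-0.27, -0.57 to 0.03) stood farthest from 0. The wildtype arrays of U2af2 differed (9.14 and 8.61), and leaving out 1 array put its value between -0.58 and -0.04. Of the paraspeckle proteins, whose scaffold RNA is Neat1, Nono (0.06) and Cpsf6 (-0.06) did.

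In the list of synaptogenesis and synaptic adhesion, 17 of 25 measured genes lay below 0 and the median was -0.03 (camera adjusted p = 0.454). Its largest values were those of Il1rapl1 (-0.22) and Lrrtm2 (-0.13). Outside the rule and after their values were seen, the synaptic adhesion genes Nlgn1 (-0.02, 95% interval -0.27 to 0.22) and Cadm1 (-0.06, -0.21 to 0.09) were also read, and with 1 array left out Nlgn1 ran from -0.15 to 0.11 and Cadm1 from -0.11 to -0.01. Presynaptic vesicle genes had a median of -0.02 over 20 genes, with Stx1a at 0.10 and Rab3a at -0.06 (camera adjusted p = 0.847). Postsynaptic glutamatergic genes had a median of 0.01 and a mean of -0.01 over 22 genes, with the camera direction downward, and Grm5 (-0.21, 95% interval -0.86 to 0.43) and Dlgap1 (-0.14) lay farthest from 0 (camera adjusted p = 0.915). The knockout arrays of Grm5 differed (8.30 and 7.53), and leaving out 1 of them gave 0.18 or -0.60. Genes of inhibitory synapses had a median of 0.00 over 12 genes, with Gabra2 at 0.08 and Gabra5 at -0.08 (camera adjusted p = 0.839).

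Immediate early genes, which neurons switch on with activity, lay above 0 in 24 of 29 cases with a median of 0.04, which did not pass (camera adjusted p = 0.112). The activity-regulated transcription factor Npas4 was at 0.36 (95% interval 0.08 to 0.65) and Klf4 at -0.48 (-1.20 to 0.25). Glucocorticoid response genes had a median of 0.00 and a mean of -0.01, the camera direction being downward, with Sult1a1 and Plin4 both at -0.12 (camera adjusted p = 0.616). Heat shock and unfolded protein response genes had a median of -0.02, with Hspa1a at -0.18 and Dnajb9 at -0.09 (camera adjusted p = 0.637). Genes of the cell cycle and targets of B-Myb had a median of 0.03, with Mcm7 at 0.15 and Mcm6 at -0.10 (camera adjusted p = 0.526). Adult neurogenesis genes had a median of 0.02 and a mean of 0.01 while camera pointed downward, with Eomes, a marker of intermediate progenitors, at 0.26 and Stmn1 at -0.18 (camera adjusted p = 0.915).

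Ribosomal protein genes had a median of -0.02, with Rps24 at -0.22 and Rpl15 at -0.18 (camera adjusted p = 0.526). Of the genes of oxidative phosphorylation, 27 of 35 lay below 0 with a median of -0.03, and Cox5a (-0.28) and Ndufs3 (-0.19) were farthest (camera adjusted p = 0.175). In the interferon list 12 of 14 genes lay above 0 with a median of 0.04, led by Irf7 at 0.19 and Usp18 at 0.11 (camera adjusted p = 0.229). No member of the synaptic, activity, stress, cell cycle, neurogenesis, ribosomal, oxidative phosphorylation or interferon lists passed the threshold by limma, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2 ribosomal protein genes, 1 synaptogenesis gene, 1 immediate early gene and 0 genes in each of the others.

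Among markers of hippocampal neurons and of other cells in or near the dissected tissue, camera called 0 lists. Dentate granule neuron markers had a median of -0.05, with 9 of 11 below 0 and Prox1 at -0.14 and Lct at -0.13 (camera adjusted p = 0.177). CA1 markers had a median of 0.04, with Man1a at 0.06 and Pou3f1 at 0.05, and CA2 and CA3 markers one of -0.02, with Amigo2 at -0.15 and Grik4 at -0.13 (camera adjusted p = 0.523 and 0.526). Interneuron markers had a median of -0.03, with the serotonin receptor Htr3a at -0.40 (95% interval -0.75 to -0.06) and the GABA synthetic enzyme Gad2 at -0.17 (-0.30 to -0.03), and camera gave an adjusted p of 0.297. Astrocyte markers had a median of 0.01 (Gfap and Aldh1l1 both 0.09), oligodendrocyte markers -0.06 (Mog -0.12, Trf -0.10) and their precursors -0.00 with a mean of 0.01 and an upward camera direction (Sox10 0.10, Cspg5 -0.09). Microglial markers had a median of -0.05 (Aif1 0.13, Csf1r -0.08) and vascular markers -0.04 (Slco1a4 -0.11, Kdr -0.07). The camera adjusted p values of these glial and vascular lists were 0.839, 0.339, 0.887, 0.297 and 0.528.

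Of the choroid plexus markers, 6 were measured and Ttr, the transthyretin gene and the most abundant of that tissue, stood at -0.54 (95% interval -0.98 to -0.10). Its log2 signal was 6.09 and 6.58 in the wildtype arrays and 5.73 and 5.86 in the knockout arrays. Folr1 was at 0.19, and the list's median was -0.04 (camera adjusted p = 0.807). Markers of thalamus and habenula (median 0.00, Calb2 0.07, Tnnt1 0.05), striatum (-0.01, Scn4b -0.09, Penk -0.08), neocortex and subiculum (-0.02, Tle4 -0.10, Fn1 -0.10) and meninges (0.02, Col1a1 0.10, Foxd1 0.08) gave camera adjusted p values of 0.847, 0.807, 0.418 and 0.616. No marker of a cell type or neighbouring tissue passed the threshold by limma, over all genes or adjusted over its list alone, and 2 interneuron markers and 1 choroid plexus marker had an unadjusted p under 0.05. Besides the neighbours of Malat1, 60 genes had the largest or second largest value of a list, and none of them was called. With 1 array left out, 14 of the 60 changed sign, Grm5, Cox5a and Grik4 among them, and 52 moved by over 1.5 times, among them U2af2, Klf4, Htr3a and Ttr.

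**Figure D2:**
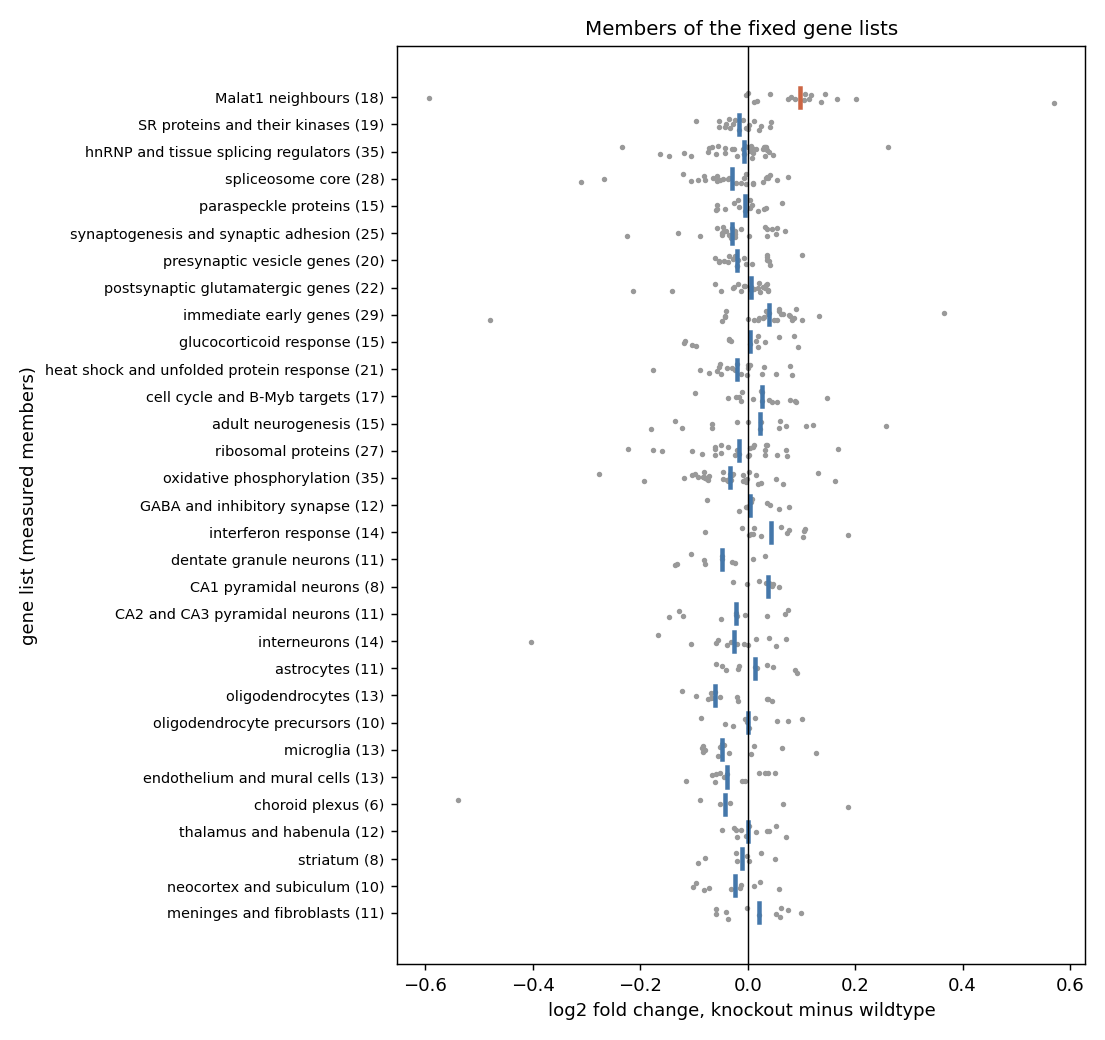
Log2 fold change, knockout minus wildtype, of each measured member (grey points) of the 31 gene lists, with the list's median as a bar. The orange bar marks the neighbours of Malat1, at 0.096, the only list called by camera with a preset correlation (adjusted p = 0.947 with an estimated correlation and 0.874 by fry); the blue bars mark lists that were not called (smallest adjusted p = 0.112).

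Over all 199133 transcript clusters above the filter, most of them without a gene name, 0 passed the adjusted threshold by limma, Malat1 included (smallest adjusted p = 0.840). At an unadjusted p under 0.05 there were 11778, against 9957 with no difference at all, and without 1 array this count ran from 8638 (without wildtype replicate 1) to 13886 (without wildtype replicate 2). Among the 25 smallest p values, Malat1 came first, and besides it 1 cluster had a gene name, Snd1 at 1.42. A brighter cluster represents Snd1 among the genes tested, and its change was under 2-fold. The largest decrease among the 25 was that of cluster 6867796, from 8.93 to 5.24 in mean log2 signal (-3.69), and cluster 6867795 was next at 8.38 and 5.07 (-3.30). The largest increase among the 25 was that of cluster 6944843, from 4.61 to 6.74 (2.13), and cluster 6816628 was next at 4.61 and 6.46 (1.86). The wildtype means of both rising clusters lay under the filter level for all clusters (4.95). The size of these rises is therefore uncertain. Snd1 and these 4 clusters were chosen after their values were seen.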

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

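The fits on every named row on its own and on the neighbour list without Neat1 and Frmd8 were chosen after seeing the data. So were the fits with 1 array left out but each gene's row kept. For the neighbour list, camera with an estimated correlation and fry were planned in the original design, beside camera with the preset correlation. Malat1 was the only gene called under the replicate block, both rescalings, both other filters, the intensity trend, the mean over rows and every named row on its own. With 1 array left out, 0 to 1 genes were called and the Malat1 change ran from -2.70 to -2.52, while genes with an unadjusted p under 0.05 numbered 451 to 1596, the most without knockout replicate 1. It lost its call without knockout replicate 1 or 2, where the lone knockout array was assumed to vary like the wildtype arrays. Transcript clusters gave 0 calls under all settings run. The neighbour list's median stayed between 0.071 and 0.106 and kept its own unadjusted camera p under 0.05 in all fits with the preset correlation. At its value of 0.096 it was not called with an estimated correlation (p = 0.126) or with fry (p = 0.0960), and it was called without Neat1 and Frmd8. The count of called lists was 0 with an estimated correlation and with fry, 2 with the filter at the 50th percentile, where immediate early genes were added, and 0 to 4 with 1 array left out. Leaving out an array also let the brightest row of a gene change. With the rows kept, the counts were 3 lists without wildtype replicate 1, 4 without knockout replicate 1, 2 without wildtype replicate 2 and 0 without knockout replicate 2, genes called were 1 without a wildtype array and 0 without a knockout array, and Malat1 was again not called at -2.52 and -2.70. The added lists changed with the array removed: oxidative phosphorylation and choroid plexus without wildtype replicate 1, oxidative phosphorylation, hnRNP regulators and heat shock genes without knockout replicate 1, oligodendrocytes without wildtype replicate 2, where immediate early genes were added only if rows could change. The cause was not tested. Same-numbered arrays deviated from their group means with a correlation of 0.06 over genes. With 2 arrays per group, this value cannot show whether the replicate numbers pair the animals. The replicate block changed no call (1 gene and 1 list, as without it), while the genes with an unadjusted p under 0.05 went from 617 to 837. Of 449 alternative values of the other list medians, 14 became called and 70 uncalled ones changed sign, as did 117 of 2390 uncalled values of 162 single genes. With the rows kept, leaving out an array moved 2 of the 23 genes named by size, Psg16 and Zfp964, by over 1.5 times. It moved 9 of the 17 neighbours besides Frmd8 by over 1.5 times and turned the sign of 5 of these neighbours. The 23 were admitted by an unadjusted limma p under 0.01 in these same arrays, which favours small gaps within groups. Their smaller share is therefore no sign that they are more reliable. Neat1 ranged from -0.70 to -0.27, the smallest with the mean over its rows, and Frmd8 from 0.50 to 0.64, neither of them called over all genes in any setting. The minimum of 3 probesets and the exon usage test were not run, since the rows are transcript clusters. No background level was used here, so how far a dim row stands above background is open.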

Other observations

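The tests on the placing and the stability of the Neat1 and Frmd8 changes, on a carried-along segment, on the neighbour list without those 2 genes and on the unnamed clusters were chosen only after the results were seen, as was the choice to leave out genes whose nearest genes include Neat1 and Frmd8 themselves, and the tests with random lists and with windows were set before their outcome was known. Around Malat1, 47 of the 60 measured genes within 30 places on either side lay above 0, and 6 had an unadjusted p under 0.05. Besides members of the list, Fau, which encodes a ribosomal protein fusion, was at 0.18 and Znhit2 at -0.16, both with an unadjusted limma p between 0.02 and 0.04. These 2 genes were picked after their values were seen. Between the rows of Malat1 and Neat1 in ID order lie 6 unnamed clusters, of which 5 had log2 fold changes below 0. The 3 lowest were -1.12, -0.85 and -0.48 and the highest was 0.05, and none passed the adjusted threshold.

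The other 2 ways of splitting the 4 arrays into pairs gave 738 (replicate 2 against replicate 1) and 671 genes (wildtype 1 and knockout 2 against the rest) at an unadjusted p under 0.05, against 617 for genotype. The genotype count was 1596 without knockout replicate 1 and 451 to 758 without 1 of the other arrays, and the other splits were not refitted without an array. Neither of them called any gene by limma after adjustment, against 1 for genotype. The neighbour list's median was 0.03 and -0.00 in those splits, against 0.096 for genotype. With 3 splits in all, no share under 0.05 can be reached.

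Neat1 was lower and Frmd8 higher in the knockout, and these are the first 2 measured genes past Malat1 on 1 side. In the rest of the genome, 0 of 15846 other genes had 2 or more of their 4 nearest measured genes changed by as much. The bar was the smaller of the Neat1 and Frmd8 changes themselves, taken after they were seen. This count therefore does not decide whether chance placed large changes beside Malat1. Over both rescalings and the 4 left-out arrays, the smallest change of either gene was 0.486 on the log2 scale. Both genes were picked for their small p in these same arrays, which favours such stability. This value therefore cannot decide whether a single array or scaling lies behind the changes. The mean over its rows, which this test left out, gave Neat1 a value of -0.27. A carried-along segment from another strain around the deletion cannot be told apart from a local effect of losing Malat1: among 40 further neighbours 4 had a p under 0.05, where binomial draws give 0 to 4, and with a lower bound of 0 no count could have argued against a segment. The labels name C57BL/6 alone, and no genotypes of flanking markers were used here, which keeps this open.

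The other neighbours of Malat1 also lay slightly above 0, which may reflect a regional effect. Chance among single genes of like brightness is argued against by 0% of 10000 matched random lists having a median as high, and their central 95% ran from -0.04 to 0.03. Shifts shared by neighbouring genes anywhere in the genome are argued against by 0% of 15460 windows of 18 consecutive genes (highest other median 0.084), and shifts of gene-dense regions by 0% of the 1168 windows at least as dense. The central 95% of the dense windows ran from -0.016 to 0.054, higher than that of all windows (-0.050 to 0.046). Dense regions thus lay slightly higher too. Windows overlap, so they are not independent. With 1 array left out, 0.136% to 0.492% of windows reached the list's median, and 0% did under both rescalings. The other 16 members, 15 of them above 0, had a mean of 0.0875, outside the central 95% of matched random lists (-0.06 to 0.04). Those lists drew genes singly, while the estimated correlation within the neighbour list was 0.159, so their range may be too narrow. Whether the shift rests on Neat1 and Frmd8 alone is therefore not decided by it. Base composition was not tested, and a carried-along segment stays open here as well.

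A run of 5 unnamed clusters that ends with 6867795 and 6867796 had log2 fold changes of -1.70 to -3.69. The knockout means of those last 2 were 5.07 and 5.24, close to the filter level for all clusters (4.95). Their falls are therefore not ranked by size against that of Malat1's named row. A candidate explanation is that the 5 clusters are rows that lie at the Malat1 locus, possibly on the other strand. The named rows on either side in ID order, Ltbp3 and Slc25a45, lie at most 3 measured genes from Malat1, and 80.7% of rows next to each other in ID order belong to genes within 5 places of each other. Positions of the rows themselves were not used here, so neither the locus nor the strand is settled.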
